A study of Mus musculus with 66 samples.

How the data were processed

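The values used were the processed values deposited by the authors, in 1 file per version of the Affymetrix murine array. The unit is not stated, and by their range the deposited values were read as intensity on a linear scale for probe sets, each a set of short oligonucleotide probes for 1 transcript. The software that made them, its method of background subtraction and the genotype and sex of the mice are not given in the sources used here, and image files and detection calls were not used here. On the later version, called Av2 in the labels, the 2% trimmed mean of every array lay within 0.011% of 800.5, and none of the values was below 0. On the earlier version, called A, the trimmed mean lay within 0.337% of 600.3, and 16.0% of the values were below 0. That every array had been scaled to a common mean was read from these values. The values were therefore used as deposited, with no further scaling.

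Intensities were raised to a floor and put on the log2 scale. On Av2 the floor was 64.7, the 20th percentile of the values on the median array. On A it was 646.8, 2 times the root mean square of the negative values. The 66 control probe sets of the manufacturer were left out of the tests. A probe set was tested where at least 2 arrays lay above the floor, which left 11997 of the 12488 probe sets on Av2 and 4742 of the 12654 on A. A further 2611 probe sets stood at 0 on every A array, and none of those is listed on Av2. Symbols came from the platform's annotation, checked by Entrez identifier against the mouse gene table of GRCm38.p6. On Av2, 10833 probe sets had 1 symbol, 396 had several and 1193 had none, and no symbol needed an update. A gene with several probe sets was represented by the brightest.

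For each version, limma was fitted with 1 mean per time point, with its moderated variance, and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The time points after injection were grouped into 6 windows, and each window's log2 change was the equally weighted mean of its time points minus the mean of the 2 control arrays. Neighbouring windows were compared in the same fit, and an F test asked whether a probe set changed at any time. Levels are given as mean ± SD of intensities, and log2 changes with the standard error from limma. A fold change against a gene at the floor on both control arrays is a lower bound, and so is the size of any change where arrays on the lower side lie at the floor. The labels do not say whether the 2 arrays of a group came from separate animals, so every p-value measures only the spread between these arrays.

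A total of 32 gene lists, holding 1073 entries of which 4 had no gene in the reference, were written from textbook knowledge. Each list was tested with limma's camera, which compares its genes with all others, with a preset correlation of 0.01 between genes and again with a correlation estimated from the arrays. The adjustment covered all lists and windows together. Counts of members that passed are given over all genes and also adjusted over the list alone. Of 192 combinations of list and window, 128 passed with the preset correlation and 44 with the estimated one, and all 44 were among the 128. A list's score on an array is the mean log2 difference of its genes from the controls.

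Named genes followed a rule. Per window, the 10 largest rises and the 10 largest falls were taken among genes past the adjusted threshold whose arrays in the window all lay on the same side of the control mean. Up to 4 members with the largest passed change were taken per list and window, and 5 rises and 5 falls per neighbouring pair of windows. Myod1, Myog, Myf5, Myf6, Pax7, Snai2, Myh3, Myh8 and Mki67 were always reported. The windows, lists, floors, tests, naming rule and most of the alternatives were chosen before the data were examined. The comparison of single time points with their neighbours, the windows without 12 h, 4 d, 9 d or 10 d, and 4 d and 10 d alone were chosen after seeing the data. So were the fits without bright probe sets, without 8 arrays low in the manufacturer's b-actin 3' probe set or without 9 low in its Gapdh 3' probe set. The lists without those 9 arrays were chosen then too.

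The alternatives tried were quantile normalization, median scaling, floors of 0.5 and 2 times the main floor, no filter on dim probe sets or a stricter filter, a variance trend with robust moderation, a required change of at least 2-fold, each array left out in turn, the number and letters in the sample codes as a block, 30 and 40 d in place of the controls, other window edges, and the time points whose codes share a number left out. For lists they were the estimated correlation, the mean of a gene's probe sets, quantile normalization, the doubled floor and each control left out.

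The fits were tested on simulated data with the same numbers of arrays. At 12 h to 2 d, 14.9% of the probe sets changed by 1.5-fold were called, 50.7% of those changed by 2-fold and 86.4% of those changed by 4-fold, with 5 false calls among 11797 unchanged probe sets. At 20 to 40 d these shares were 10.4%, 58.2% and 90.9%, and at 10 d on the earlier array 7.5%, 34.3% and 77.3%. A list of matrix genes shifted by 0.5 log2 was called with both correlations, with 0 false calls among the other lists. The simulated genes varied independently, so false list calls from correlated genes were not tested. The number of arrays per group, 2, limits the precision. The work used R 4.3.3, limma 3.58.1, the R package data.table at 1.17.8, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.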

Results

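Gene expression was measured in mouse gastrocnemius, a calf muscle, left untreated or taken at times from 12 h to 40 d after an injection of cardiotoxin, a snake venom toxin that destroys muscle fibres and leaves the satellite cells that rebuild them. The labels of 10 arrays give the injection as 100 ul of 10 uM cardiotoxin, and those of 4 control arrays give an age of 8 weeks. The labels name temporal profiling of muscle regeneration as the subject. Snai2, also called Slug, was followed as well, since it has been studied as a possible target of Myod1 in regenerating muscle. Of the 66 arrays, 54 were of the later version and held untreated controls and 26 times after injection, with 2 arrays in each of the 27 groups. The other 12 arrays were of the earlier version, with 2 each for controls, 12 h, 1 d, 2 d, 4 d and 10 d. The controls and the 12 h samples carry the same codes on both versions. On the later version, between 76.4% and 83.4% of the probe sets of an array lay above the floor, and the median intensity of an array lay between 301.7 and 362.7. On the earlier version 26.4% to 28.5% lay above the floor.

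Of 11997 probe sets tested, 5837 (48.7%) changed over the time course. Against the controls, 4348 changed at 12 h to 2 d (12 h, 1 and 2 d; n = 6), 4886 at 3 to 4.5 d (n = 8), 4211 at 5 to 7.5 d (n = 12), 3684 at 8 to 10 d (n = 10), 2900 at 11 to 16 d (n = 10) and 855 at 20 to 40 d (20, 30 and 40 d; n = 6). All windows share the same 2 control arrays.

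**Figure D1:**
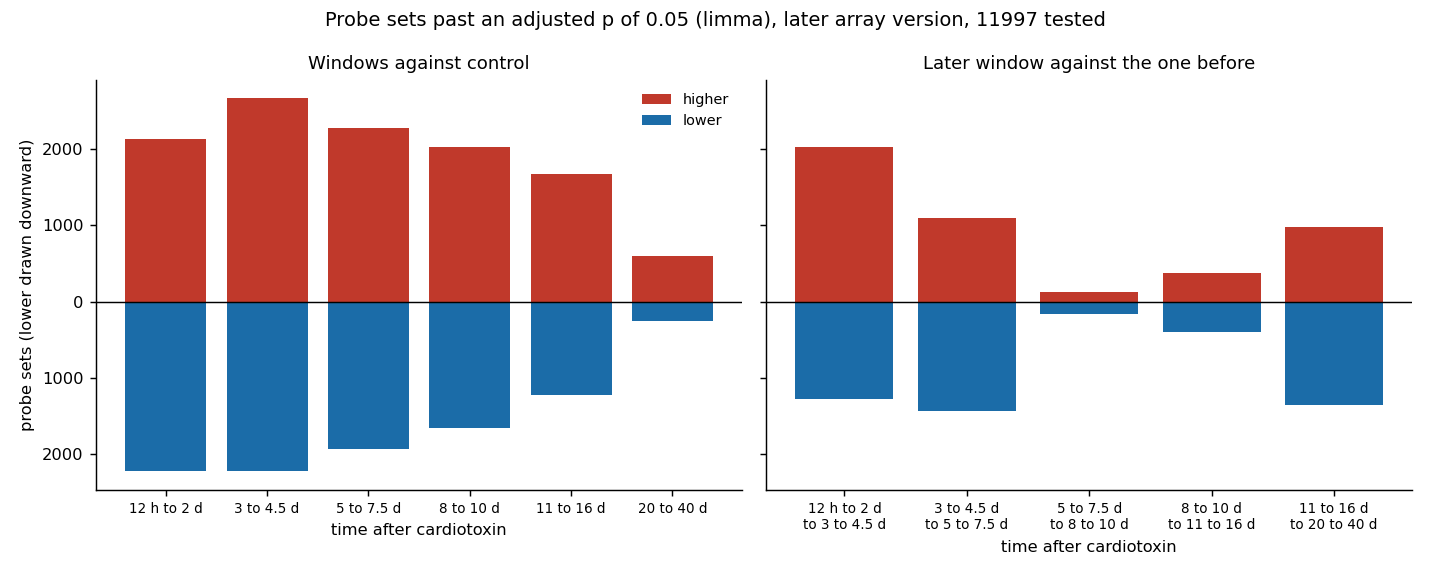
Number of probe sets called higher (upward bars) and lower (downward bars) than in untreated muscle, per window of time after injection, of 11997 tested. The calls went from 4886 at 3 to 4.5 d down to 855 at 20 to 40 d.

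The regulators of muscle formation were followed singly, to time Snai2 against Myod1. Myod1, a transcription factor that commits satellite cells to muscle, had its highest mean at 3 d, 7802 ± 1150 (n = 2) against 2175 ± 475 in untreated muscle, which is 3.59-fold. Myog, which drives differentiation, had its highest mean at 3.5 d, 11270 ± 985 against 781 ± 165 (14.4-fold). Myh3, the embryonic myosin heavy chain, went from 163.2 ± 4.4 to 9982 ± 2350 at 5.5 d (61.2-fold), and Myh8, the perinatal one, from 299.2 ± 68.0 to 3908 ± 655 at 5.5 d (13.1-fold). Each of the 4 changed over the time course (adjusted p = 3.4e-10, 5.5e-11, 3.9e-17 and 5.7e-17). With 1 array left out, the highest mean of Myog moved between 3 and 3.5 d, that of Myh3 between 4.5 and 5.5 d and that of Myh8 between 5.5 and 6.5 d. Myf6, a regulator found in mature fibres, stood at 3156 ± 119 in controls, had its highest mean of 6150 ± 2930 at 12 h (1.95-fold), and fell at 3 to 4.5 d (log2 change -1.75, SE 0.30, adjusted p = 1.5e-05). Myf5, a marker of committed satellite cells, had its highest mean of 368.1 ± 29.8 at 3.5 d against 130 ± 64.6, which moved between 3.5 and 5 d with 1 array left out. Its change at 3 to 4.5 d (0.89, SE 0.31, adjusted p = 0.020) did not pass without control replicate 1 (adjusted p = 0.582). Pax7, the marker of quiescent satellite cells, was not measured.

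Snai2, a transcriptional repressor of the Snail family, stood at 650.2 ± 178 in controls and had its highest mean at 6 d, 2199 ± 181 (3.38-fold, F test adjusted p = 2.7e-09). The highest mean lay between 6 and 10 d when single arrays were left out. Myod1 also stood at 4642 ± 990 at 12 h, but its change at 12 h to 2 d (0.48, SE 0.17, adjusted p = 0.025) ended without each of 3 arrays in turn, with the highest adjusted p without control replicate 1 (0.456). Snai2 rose from 12 h to 2 d to 3 to 4.5 d by 1.20 log2 (SE 0.11, adjusted p = 9.8e-10), as did Myod1 by 1.02 (SE 0.11, adjusted p = 1.4e-08). From there Myod1 fell to 5 to 7.5 d (log2 change -0.86, SE 0.09, adjusted p = 8.0e-08), while Snai2 changed by 0.16 (SE 0.10), which did not pass. Snai2 was 1.47 log2 above the controls at 8 to 10 d (SE 0.16) and 1.14 at 11 to 16 d (SE 0.16), windows in which Myod1 stood at 0.39 (SE 0.16, adjusted p = 0.067) and -0.09 (SE 0.16). At 20 to 40 d the change of Snai2, 0.52 (SE 0.17), did not pass (adjusted p = 0.067). The difference between the courses of Snai2 and Myod1 was not tested.

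**Figure D2:**
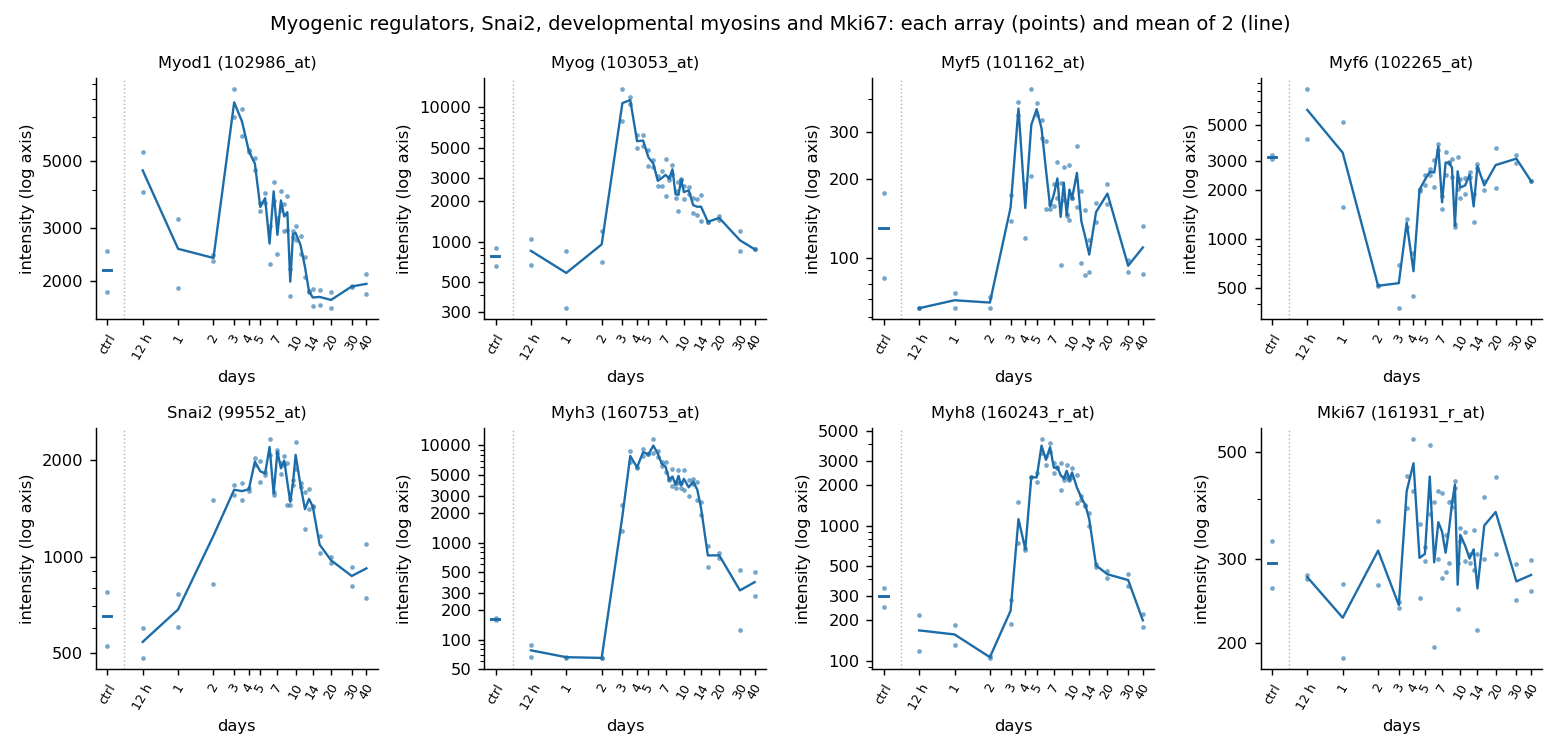
Intensity (log axis) of 8 regulators and myosins against days after injection, with a point per array and a line through the mean of the 2 arrays of each time. Myod1 stands highest at 3 d (7802), Myog at 3.5 d (11270), Snai2 at 6 d (2199) and Myh3 at 5.5 d (9982).

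In the 12 h to 2 d after injection, genes of white blood cells rose from near the floor to high intensities. S100a8, an abundant calcium-binding protein of neutrophils, rose 235-fold, from 96.7 ± 23.2 in untreated muscle (n = 2) to 24380 ± 11420 (n = 6; log2 change 7.88, SE 0.66, adjusted p = 5.4e-11). Its partner S100a9 lay at the floor on both controls and rose at least 164-fold to 11120 ± 3342. Ccl2, the chemokine that draws monocytes, rose at least 232-fold to 15100 ± 1903 (7.86, SE 0.27, adjusted p = 2.7e-19). Arg1, an enzyme of macrophages, rose at least 197-fold (7.62, SE 0.65), with the 12 h arrays at 15546 and 1857. Adam8, a metalloprotease of white cells, rose at least 184-fold. The rises of Chil3, Cxcl5, Mmp9 and Ccl7, each above the floor on 1 of 2 controls, lay between 84.7-fold and 140-fold, and that of Il4ra, the receptor for interleukin 4, was 92.4-fold. Genes of mature fibres were among the largest falls. Aqp4, the water channel of fast fibres, fell from 1975 ± 249 to 221 ± 318 (-3.96, SE 0.57, adjusted p = 1.4e-06). Phkg1, a subunit of phosphorylase kinase (-3.55, SE 0.34), Fabp3, a fatty acid carrier (-3.43, SE 0.40), and Ache, acetylcholinesterase (-3.44, SE 0.46), fell too, as did Dnajb5, a co-chaperone (-3.96, SE 0.56), Dbp, of the circadian clock (-3.85, SE 0.45), and Tspan8, a membrane protein (-3.48, SE 0.42). In all, 2126 probe sets were higher and 2222 lower, and 2525 were called with a required change of at least 2-fold. On 12 h replicate 2 and both arrays of 1 and 2 d, the manufacturer's b-actin 3' probe set was low. It lay at 0.033 to 0.078 of its 5' probe set, against 0.725 and 1.057 in controls. This window was not counted without these arrays.

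Among neutrophil markers, 15 of 22 rose and none fell (camera adjusted p = 1.1e-09), and the same count held adjusted over the list alone. Of 34 acute cytokines and chemokines 27 rose (28 adjusted over the list alone; adjusted p = 5.2e-17), and of 49 markers of monocytes and macrophages 45 rose (45 adjusted over the list alone; 8.7e-29), among them Ccr2, the receptor for Ccl2, 52.1-fold, and Cd53, 69.8-fold. Stress and immediate early genes rose in 34 and fell in 2 of 47 (34 and 2 adjusted over the list alone; 5.7e-14), with Bcl3 at 4.25 log2 (SE 0.47), the metal-binding Mt1 at 3.64 (SE 0.16) and the haem-degrading Hmox1 at 3.59 (SE 0.24). Lysosomal genes rose in 25 and fell in 1 of 32 (25 and 1 adjusted over the list alone; 1.5e-10), such as the lipase Lipa (2.86, SE 0.24). Cell cycle genes rose in 40 and fell in 2 of 79 (44 and 2 adjusted over the list alone; 6.2e-07). Each of these 6 calls also passed with an estimated correlation. Interferon response genes rose in 26 of 36 (27 adjusted over the list alone; 8.8e-08), but adjusted p = 0.13 with an estimated correlation.

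Genes of energy metabolism fell together at 12 h to 2 d. Of 71 genes of oxidative phosphorylation and the citric acid cycle, 60 fell and 1 rose (60 and 1 adjusted over the list alone; adjusted p = 4.7e-21), with the muscle subunits Cox7a1 at -3.36 log2 (SE 0.46) and Cox8b at -3.02 (SE 0.30). That call had adjusted p = 0.091 with an estimated correlation. Fatty acid genes fell in 20 of 22 (21 adjusted over the list alone; 7.1e-10), and adjusted p = 0.091 with an estimated correlation. Glycolysis and glycogen genes fell in 15 and rose in 1 of 19 (17 and 1 adjusted over the list alone; 1.0e-07), and adjusted p = 0.10 with an estimated correlation. Adult fast contractile genes fell in 15 and rose in 1 of 25 (16 and 1 adjusted over the list alone; 3.7e-06), such as Ryr1, the calcium release channel (-2.94, SE 0.29), and adjusted p = 0.14 with an estimated correlation. Imprinted growth genes fell in 11 of 18 (11 adjusted over the list alone; adjusted p = 0.0040, and 0.039 with an estimated correlation), most of all Cdkn1c, an inhibitor of the cell cycle (-2.13, SE 0.21). The labels give no hour of collection. For clock genes, here and in later windows, a different hour from the controls cannot be told apart from injury. Circadian clock genes fell in 6 and rose in 1 of 13 (6 and 1 adjusted over the list alone; adjusted p = 0.049). That call had adjusted p = 0.12 with an estimated correlation and ended without control replicate 2 (0.0689) and with the mean of a gene's probe sets (0.0634).

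Markers of lymphocytes did not move as a list at 12 h to 2 d. Of 25 genes in the list T and natural killer cells 1 rose and 1 fell, as when adjusted over the list alone (adjusted p = 0.79), and Il7r, the interleukin 7 receptor, was the rise (2.31, SE 0.34). For the list B and plasma cells the adjusted p was 0.99, with 1 rise and 1 fall of 16 and none adjusted over the list alone. The 12 h arrays differed in this list, with scores of -0.11 on replicate 1 and 1.70 on replicate 2. The list antigen presentation by class II, scored 0.18 and 1.89 on the same arrays, rose in 5 of 18 (5 adjusted over the list alone; adjusted p = 0.014), and adjusted p = 0.35 with an estimated correlation. Without 12 h, 4614 probe sets were called in the window, against 4348 with it. Erythroid genes fell in 1 of 8 (adjusted p = 0.61; 1 adjusted over the list alone). Matrix genes rose in 20 and fell in 10 of 61 (20 and 12 adjusted over the list alone; adjusted p = 0.28), with a median change of -0.066 and a mean of 0.324, which differ in sign, and passed as a list without control replicate 1 (0.0322).

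At 3 to 4.5 d genes of forming fibres were high beside those of macrophages and of dividing cells. Chrng, the fetal subunit of the acetylcholine receptor, rose 45.6-fold from 77.5 ± 18.1 (1 of 2 controls above the floor) to 3599 ± 935 (n = 8; log2 change 5.51, SE 0.40, adjusted p = 1.5e-12). Myh3 rose 31.5-fold to 6041 ± 2862 (4.98, SE 0.31), and Tgfb1, a growth factor of repair, 39.3-fold to 2781 ± 704 (1 of 2 controls above the floor). Macrophage genes stood high as well, with Ccr2 at 48.9-fold, the antibody receptor Fcgr2b at 38.2-fold and Tyrobp, a signalling adaptor, at 32.9-fold (all 8 arrays above the control mean). Ccl2 was at least 66.4-fold and Adam8 at least 49.8-fold higher. The slow light chain Myl3 fell from 16960 ± 678 to 397 ± 208 (-5.71, SE 0.68, adjusted p = 3.1e-08). The other slow light chain Myl2 (-4.60, SE 0.63), Cox7a1 (-4.87, SE 0.44), Ckmt2, mitochondrial creatine kinase (-4.23, SE 0.31), and the glucose transporter Slc2a4 (-4.17, SE 0.43) fell too. In this window 2664 probe sets were higher (54.5%, but 46.2% under median scaling and 48.5% under quantile normalization) and 2222 lower, and 2920 were called with a required change of at least 2-fold.

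Cell cycle genes rose in 63 and fell in 1 of 79 at 3 to 4.5 d (66 and 1 adjusted over the list alone; adjusted p = 2.4e-18, and 0.00086 with an estimated correlation). Cdk1, the kinase that starts mitosis, rose 22.0-fold (4.46, SE 0.45), and Prc1 and Kif20a, of the mitotic spindle, at least 19.8-fold and at least 19.1-fold. The brightest probe set of Mki67, a marker of dividing cells, did not change (F test adjusted p = 0.0856), while another Mki67 probe set rose by 4.07 log2 (SE 0.25, adjusted p = 7.4e-14). Myogenic regulators and satellite cell genes rose in 13 and fell in 4 of 24 (15 and 4 adjusted over the list alone; 0.0088, and 0.028 with an estimated correlation), led by Myog (3.33, SE 0.27) and Fgfr4, a growth factor receptor of new myotubes (at least 9.69-fold). Developmental sarcomere genes rose in 8 and fell in 1 of 14 (9 and 1 adjusted over the list alone; 0.00053), among them the cardiac-type Tnnt2, 20.1-fold, and adjusted p = 0.074 with an estimated correlation. The list of Snai2 and related mesenchymal regulators rose in 10 of 19 (12 adjusted over the list alone; 0.0016), with Runx1 16.3-fold (1 of 2 controls above the floor), Sox11 7.65-fold and Cdh2 6.53-fold, but adjusted p = 0.091 with an estimated correlation. Imprinted growth genes, lower in the window before, rose in 10 and fell in 3 of 18 (10 and 3 adjusted over the list alone; 0.0088), such as Mest (3.37, SE 0.34) and Peg3 (3.24, SE 0.29), and adjusted p = 0.060 with an estimated correlation. Ribosomal protein genes rose in 16 of 32 (16 adjusted over the list alone; 0.011), and adjusted p = 0.22 with an estimated correlation.

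Lysosomal genes rose in 25 and fell in 1 of 32 (26 and 1 adjusted over the list alone; adjusted p = 4.2e-12, and 0.031 with an estimated correlation), such as the protease Lgmn (3.60, SE 0.21). Glycolysis and glycogen genes fell in 17 and rose in 1 of 19 at 3 to 4.5 d (18 and 1 adjusted over the list alone; adjusted p = 1.6e-10), with Phkg1 at -4.97 log2 (SE 0.33), and adjusted p = 0.060 with an estimated correlation. Slow contractile genes fell in 5 and rose in 1 of 8 (6 and 1 adjusted over the list alone; 0.0026), with Mb, the oxygen store, at -3.35 (SE 0.29), and adjusted p = 0.25 with an estimated correlation. The list slow contractile scored -3.79 and -3.91 on the 4 d arrays, against -1.98 and -2.16 at 3.5 d and -1.90 and -1.46 at 4.5 d. The 4 d arrays differed from both neighbouring times at 813 probe sets, and 4871 probe sets were called in the window without 4 d, against 4886 with it. Adipocyte genes fell in 9 and rose in 1 of 15 (9 and 1 adjusted over the list alone; 0.0079), such as Gpd1, of glycerol metabolism (-3.71, SE 0.34), and adjusted p = 0.13 with an estimated correlation. Gpd1 is also in the list glycolysis and glycogen, so its fall is not particular to adipocytes. The calls of Cidec and Retn ended without control replicate 1. With single arrays left out, their changes lay at -2.385 to -1.057 and -2.463 to -1.875 log2. Circadian clock genes fell in 8 and rose in 2 of 13 (8 and 2 adjusted over the list alone; 0.0023, and 0.028 with an estimated correlation), with Dbp at -3.81 (SE 0.44) and Nr1d2 at -2.30 (SE 0.16). Growth factors of regeneration rose in 7 and fell in 8 of 31 (7 and 8 adjusted over the list alone; 0.97), and smooth muscle genes rose in 2 and fell in 2 of 8 (2 and 2 adjusted over the list alone; 0.99). Proteasome and atrophy ligase genes fell in 11 and rose in 1 of 34 (11 and 1 adjusted over the list alone; 0.018), a call with adjusted p = 0.41 with an estimated correlation and 0.0716 under quantile normalization. Neutrophil genes rose in 9 of 22 (9 adjusted over the list alone; 0.045), with adjusted p = 0.40 with an estimated correlation. That call ended with the doubled floor (0.113), without control replicate 1 (0.0757) and without control replicate 2 (0.0504).

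At 5 to 7.5 d genes of white cells, the matrix and embryonic muscle led the rises. Mmp12, the elastase of macrophages, rose 45.1-fold from 121.7 ± 80.7 (1 of 2 controls above the floor) to 5071 ± 1550 (n = 12; log2 change 5.49, SE 0.31, adjusted p = 1.4e-14). Postn, a matrix protein of healing tissue, rose 26.8-fold from 1106 ± 775 to 26200 ± 5632 (4.74, SE 0.28). Myh3 rose 42.6-fold to 7214 ± 2042 (5.41, SE 0.30), and Myl4, the embryonic light chain, 25.4-fold to 13070 ± 3684 (4.67, SE 0.27). C1qtnf3, a secreted protein related to complement C1q, rose 24.8-fold, Csrp2, a LIM-domain protein, 26.1-fold (1 of 2 controls above the floor) and Sirpa, a receptor of macrophages, 20.9-fold. Adam8 was at least 27.8-fold and the chemokine Ccl8 24.0-fold higher. Myl3 (-5.05, SE 0.65), Aqp4 (-4.19, SE 0.54) and Phkg1 (-3.58, SE 0.32) were still lower than in untreated muscle, as were Plin4, a lipid droplet protein (-3.26, SE 0.32), and Ces1d, a lipase (-3.50, SE 0.33). In this window 2276 probe sets were higher and 1935 lower, but 2021 higher and 2343 lower under median scaling and 2031 and 2236 under quantile normalization, and 2248 were called with a required change of at least 2-fold.

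Extracellular matrix genes rose in 50 and fell in 3 of 61 at 5 to 7.5 d, with the same counts adjusted over the list alone (adjusted p = 1.9e-20, and 0.0023 with an estimated correlation). Tnc, tenascin C, rose 18.1-fold (4.18, SE 0.32), and Lox, which crosslinks collagen, 13.9-fold (3.80, SE 0.20). Developmental sarcomere genes rose in 10 of 14 (10 adjusted over the list alone; 1.2e-06, and 0.023 with an estimated correlation). Imprinted growth genes rose in 12 and fell in 2 of 18 (12 and 3 adjusted over the list alone; 3.4e-05, and 0.0081 with an estimated correlation), with Mest 14.5-fold, Peg3 11.9-fold and Plagl1 11.9-fold higher. Fibroblast and fibro-adipogenic genes rose in 11 and fell in 2 of 22 (11 and 3 adjusted over the list alone; 0.0034), with S100a4 at 2.83 (SE 0.15) and Thy1 at 2.20 (SE 0.20), and adjusted p = 0.14 with an estimated correlation. Class II antigen presentation genes rose in 8 of 18 (8 adjusted over the list alone; 0.00039), such as the chain H2-Aa (2.67, SE 0.31), and adjusted p = 0.19 with an estimated correlation. Complement genes rose in 9 and fell in 1 of 13 (9 and 1 adjusted over the list alone; 3.8e-05), with the subunits C1qb at 3.03 (SE 0.17) and C1qc at 2.74 (SE 0.15), and adjusted p = 0.060 with an estimated correlation.

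Neuromuscular junction genes rose in 6 of 12 at 5 to 7.5 d (6 adjusted over the list alone), which did not pass as a list (adjusted p = 0.054) but did under quantile normalization (0.0390) and without control replicate 1 (0.0315). Oxidative phosphorylation genes still fell in 53 and rose in 1 of 71 (57 and 1 adjusted over the list alone; 1.1e-15), but adjusted p = 0.14 with an estimated correlation. Fatty acid genes fell in 21 of 22 (21 adjusted over the list alone; 1.4e-11), with Pdk4, a brake on glucose oxidation, at -2.43 (SE 0.29), and adjusted p = 0.072 with an estimated correlation. Schwann cell and nerve genes rose in 1 and fell in 2 of 13 (1 and 2 adjusted over the list alone) and did not pass (0.41). The falls were Mbp, of myelin (-1.16, SE 0.22), and Mal (-0.92, SE 0.33), which did not pass without control replicate 1 (0.661), and the rise was the receptor Erbb3 (1.23, SE 0.19). Erythroid genes fell in 3 of 8 (3 adjusted over the list alone; 0.040), such as Bpgm (-2.52, SE 0.29), and adjusted p = 0.25 with an estimated correlation. That call ended under quantile normalization (0.0573) and without control replicate 1 (0.101).

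**Figure D3:**
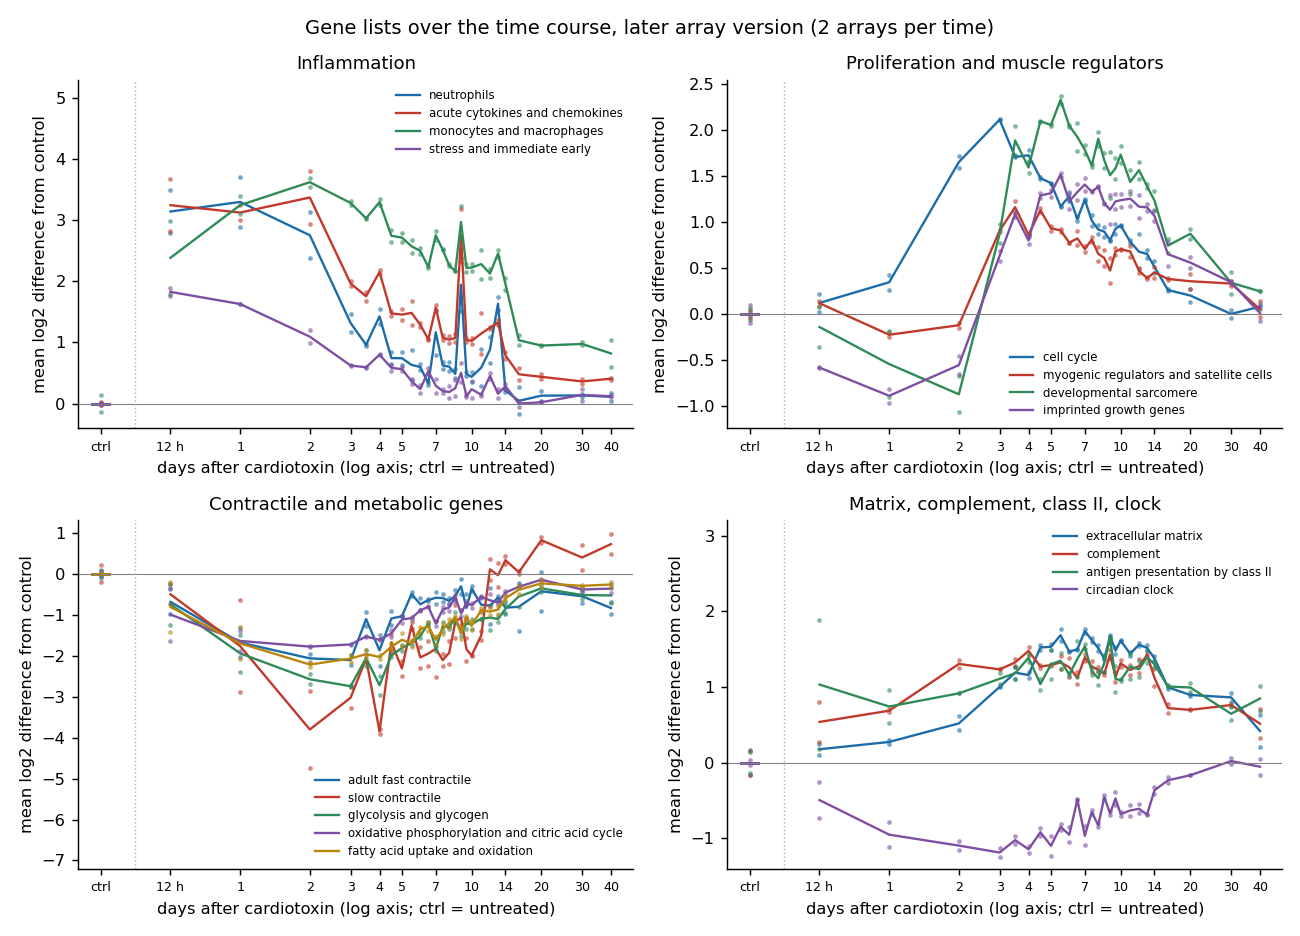
Scores of gene lists (mean log2 difference of a list's genes from the controls) per array against days after injection on a log axis, in 4 panels. The neutrophil list stands highest at 1 d (3.3), the cell cycle list at 3 d (2.11), the developmental sarcomere list at 5.5 d (2.33) and the extracellular matrix list at 7 d (1.74).

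At 8 to 10 d macrophage and matrix genes were high and several fibre genes still low. Mmp12 rose 51.3-fold to 5693 ± 1496 (n = 10; log2 change 5.68, SE 0.31, adjusted p = 2.2e-14; 1 of 2 controls above the floor), and Postn 24.9-fold to 24370 ± 5177 (4.64, SE 0.28). Ctss, a lysosomal protease of macrophages, rose from 1189 ± 320 to 21600 ± 4618 (18.2-fold; 4.18, SE 0.19). Myh3 was 26.5-fold higher, at 4396 ± 888 (4.73, SE 0.31). Tyrobp rose 16.9-fold, Sirpa 16.9-fold and Cd53, of white cells, 17.4-fold. Myl3 stood at 1484 ± 1011 (-3.78, SE 0.66) and Aqp4 at 194 ± 95.0 (-3.50, SE 0.54), both lower than in untreated muscle. Tlcd4, a membrane protein (-3.03, SE 0.30), and Inmt, a methyltransferase (-2.87, SE 0.43), were also lower. The slow heavy chain Myh7 fell as well (-2.92, SE 0.72, adjusted p = 0.0020), a call that ended without control replicate 2 (0.0654). In this window 2025 probe sets were higher and 1659 lower, but 1824 higher and 2025 lower under median scaling and 1833 and 1964 under quantile normalization, and 1833 were called with a required change of at least 2-fold. Without control replicate 2, the count was 2443 instead of 3684.

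Extracellular matrix genes rose in 50 and fell in 3 of 61 at 8 to 10 d (50 and 3 adjusted over the list alone; adjusted p = 4.9e-23, and 0.0019 with an estimated correlation), and macrophage genes rose in 44 of 49 (46 adjusted over the list alone; 2.0e-29, and 0.023 with an estimated correlation). Developmental sarcomere genes rose in 9 of 14 (10 adjusted over the list alone; 1.2e-06, and 0.023 with an estimated correlation) and imprinted growth genes rose in 11 and fell in 2 of 18 (11 and 2 adjusted over the list alone; 2.0e-05, and 0.0068 with an estimated correlation). Acute cytokines and chemokines rose in 18 of 34 (18 adjusted over the list alone; 1.8e-06), with Ccl8 13.9-fold higher, and adjusted p = 0.090 with an estimated correlation. Within this window the list acute cytokines and chemokines scored 3.18 and 2.32 on the 9 d arrays, against 1.01 and 1.13 at 8.5 d and 1.07 and 1.01 at 9.5 d. The count of the window was 3453 without 9 d and 3632 without 10 d. Neuromuscular junction genes rose in 6 of 12 (6, with 1 fall, adjusted over the list alone; 0.049), led by Chrng, 14.3-fold higher (1 of 2 controls above the floor). That call had adjusted p = 0.12 with an estimated correlation and ended without control replicate 2 (0.106) and without the 9 arrays of the later version that were low in the manufacturer's Gapdh 3' probe set (0.0632).

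Slow contractile genes fell in 5 and rose in 1 of 8 at 8 to 10 d (5 and 1 adjusted over the list alone; adjusted p = 0.012), with Tpm3 at -2.24 (SE 0.35), and adjusted p = 0.33 with an estimated correlation. Adult fast contractile genes fell in 7 and rose in 1 of 25 (7 and 1 adjusted over the list alone; 0.012), with Ryr1 at -1.39 (SE 0.27) against Tpm1, a tropomyosin, at 1.49 (SE 0.14). That call had adjusted p = 0.41 with an estimated correlation and 0.221 under quantile normalization. Pvalb, a calcium buffer of fast fibres, and Acta1, skeletal actin, stood over 8-fold apart between the 9.5 d arrays, at 17217 and 487.3 and at 18243 and 1089.3. Proteasome and atrophy ligase genes fell in 10 of 34 (10 adjusted over the list alone; 0.0070), such as Ube2b (-1.99, SE 0.21), and adjusted p = 0.35 with an estimated correlation. Ribosomal protein genes rose in 9 of 32 (9 adjusted over the list alone; 0.049), with adjusted p = 0.32 with an estimated correlation. That call ended without control replicate 1 (0.124) and with the mean of a gene's probe sets (0.114). Myogenic regulators and satellite cell genes rose in 8 and fell in 1 of 24 (10 and 2 adjusted over the list alone; 0.049), with Notch1, a receptor of satellite cells, at 2.30 (SE 0.35), and adjusted p = 0.082 with an estimated correlation. That call ended with the doubled floor (0.107), the mean of a gene's probe sets (0.121), without control replicate 1 (0.0805) and without the 9 arrays low in the Gapdh 3' probe set (0.0568).

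At 11 to 16 d matrix, macrophage and embryonic muscle genes led the rises. Mmp12 was 39.1-fold higher, at 5347 ± 2718 (n = 10; log2 change 5.29, SE 0.31, adjusted p = 2.7e-13; 1 of 2 controls above the floor), and Postn 19.3-fold, at 19390 ± 5200 (4.27, SE 0.28). Kcne1l, a subunit of potassium channels, rose 15.3-fold from 84.7 ± 4.6 to 1387 ± 479 (3.93, SE 0.37). Myh3 was 14.9-fold higher, at 2893 ± 1425 (3.90, SE 0.31), Ctss 12.8-fold and Ccr2 11.1-fold. Mstn, myostatin, which limits muscle growth, fell from 1880 ± 21.3 to 399 ± 168 (-2.34, SE 0.37, adjusted p = 1.2e-05). Ces1d (-3.31, SE 0.33), Inmt (-2.77, SE 0.43) and Smyd2, a methyltransferase of muscle (-3.17, SE 0.70), were lower too. Aqp4 fell as well (-2.23, SE 0.54, adjusted p = 0.0025), a call that ended without control replicate 1 (0.0544). In this window 1671 probe sets were higher (57.6%, but 48.7% under median scaling) and 1229 lower, and 1266 were called with a required change of at least 2-fold. Of its time points, only 16 d has codes that do not share a number. Without control replicate 2 the count was 1659 instead of 2900, and it was 807 without the time points whose codes share a number.

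Interferon response genes rose in 28 of 36 at 11 to 16 d (30 adjusted over the list alone; adjusted p = 5.7e-14, and 0.045 with an estimated correlation), such as Irf7, which amplifies the response (2.88, SE 0.30), and Psmb9, of the immunoproteasome (2.56, SE 0.26; 1 of 2 controls above the floor). Complement genes rose in 9 of 13 (10 adjusted over the list alone; 5.4e-08, and 0.023 with an estimated correlation), such as the receptor C3ar1 (2.41, SE 0.19). Fibroblast and fibro-adipogenic genes rose in 15 and fell in 1 of 22 (16 and 1 adjusted over the list alone; 1.0e-07, and 0.023 with an estimated correlation), such as Serpinf1 (1.66, SE 0.20) and the matrix protein Dpt (1.56, SE 0.30). The list of Snai2 and related mesenchymal regulators rose in 8 of 19 (8 adjusted over the list alone; 0.00037), with Runx1 at 2.35 (SE 0.36; 1 of 2 controls above the floor) and Id2 at 1.47 (SE 0.19), and adjusted p = 0.066 with an estimated correlation. Growth factors of regeneration rose in 12 and fell in 6 of 31 (12 and 6 adjusted over the list alone; 0.040), with Sfrp2, a binder of Wnt proteins, at 2.56 (SE 0.24), and adjusted p = 0.090 with an estimated correlation. Endothelial genes rose in 10 and fell in 1 of 29 (10 and 1 adjusted over the list alone; 0.036), with Cd93 at 2.10 (SE 0.15). That call had adjusted p = 0.22 with an estimated correlation and ended without control replicate 2 (0.0914).

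Slow contractile genes no longer differed as a list at 11 to 16 d, with 1 of 8 higher, as when adjusted over the list alone (adjusted p = 0.75). Oxidative phosphorylation genes fell in 34 and rose in 1 of 71 (41 and 1 adjusted over the list alone; 1.2e-09), with Cycs, cytochrome c, at -1.25 (SE 0.27), and adjusted p = 0.26 with an estimated correlation. Adult fast contractile genes fell in 8 and rose in 1 of 25 (9 and 1 adjusted over the list alone; 0.0015), a call with adjusted p = 0.30 with an estimated correlation and 0.0745 under quantile normalization. Among them Pvalb fell (-3.18, SE 1.14), a call that ended without each of 7 arrays in turn, with the highest adjusted p without control replicate 2 (0.267). Its 12 d arrays stood at 22733 and 607.4. Acta1 stood at 28507 and 1587 on the 16 d arrays. Circadian clock genes fell in 5 and rose in 1 of 13 (5 and 1 adjusted over the list alone; 0.011), with Per2 at -1.61 (SE 0.22) against Arntl at 1.03 (SE 0.20), and adjusted p = 0.060 with an estimated correlation. As before, a different hour of collection cannot be told apart from injury for these genes.

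At 20 to 40 d fewer genes differed than before, and matrix and macrophage genes were prominent among them. Mmp12 was 8.64-fold higher, at 979 ± 350 (n = 6; log2 change 3.11, SE 0.33, adjusted p = 3.4e-07; 1 of 2 controls above the floor). Postn was 4.82-fold higher, at 5585 ± 3081 (2.27, SE 0.30), Ccr2 5.32-fold, at 587 ± 141 (2.41, SE 0.31), and Mrc2, a collagen receptor, 4.60-fold, at 651 ± 138 (2.20, SE 0.30). Cyfip2, a regulator of actin, rose 5.96-fold (2.58, SE 0.31; 1 of 2 controls above the floor), and Myd88, an adaptor of innate immunity, 4.46-fold (2.16, SE 0.24). Mstn stood at 484 ± 98.8, 3.95-fold lower than in controls (-1.98, SE 0.39, adjusted p = 0.0013). Wnt4, a secreted signal, fell 3.83-fold from 282.9 ± 4.8 (-1.94, SE 0.16, adjusted p = 1.2e-09). Igkv6-23, of an antibody light chain, rose by 3.67 log2 (SE 0.90, adjusted p = 0.0097; 1 of 2 controls above the floor) with a spread of 2623 ± 4862, a call that ended without each of 2 arrays in turn, with the highest adjusted p without control replicate 2 (0.101). Higher probe sets made up 70.3% of the calls, 601 against 254, but 56.7% under median scaling. The count of 855 was 417 without control replicate 2 and 495 without control replicate 1, 476 without the arrays low in the Gapdh 3' probe set, and 361 with a required change of at least 2-fold.

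Extracellular matrix genes rose in 34 of 61 at 20 to 40 d and none fell (36, with 1 fall, adjusted over the list alone; adjusted p = 6.9e-22, and 0.0021 with an estimated correlation), such as Fbln2, of elastic fibres (1.36, SE 0.15). Macrophage genes rose in 24 of 49 (34 adjusted over the list alone; 4.7e-21, and 0.039 with an estimated correlation), with Ctss at 2.01 (SE 0.20). Fibroblast and fibro-adipogenic genes rose in 9 of 22 (17 adjusted over the list alone; 9.6e-09, and 0.018 with an estimated correlation), with Tnxb, of the matrix, at 1.05 (SE 0.19). Complement genes rose in 7 of 13 (8 adjusted over the list alone; 1.0e-07, and 0.025 with an estimated correlation), and growth factors of regeneration rose in 7 and fell in 2 of 31 (10 and 2 adjusted over the list alone; 0.0070, and 0.031 with an estimated correlation). The calls of C1qb, C2 and C3ar1 ended without control replicate 2. With single arrays left out, their changes lay at 0.493 to 1.379, 0.904 to 1.11 and 0.581 to 1.184 log2. Those of Sfrp4 and Tgfb1 also ended without control replicate 2, and that of Fst without control replicate 1. Neuromuscular junction genes rose in 3 of 12 (4 adjusted over the list alone; 0.0043, and 0.031 with an estimated correlation). They were Agrn, Chrng and Utrn, and none of the 3 passed without control replicate 2 (0.251, 0.149 and 0.642). Class II antigen presentation genes rose in 6 of 18 (6 adjusted over the list alone; 1.3e-05), with Cd74 at 1.86 (SE 0.32), and adjusted p = 0.12 with an estimated correlation. The calls of H2-Aa, H2-Ab1 and H2-DMa ended without control replicate 2. With single arrays left out, their changes lay at 1.437 to 2.233, 0.995 to 1.488 and 1.158 to 2.227 log2. Interferon response genes rose in 9 of 36 (17 adjusted over the list alone; 6.9e-10), and adjusted p = 0.091 with an estimated correlation.

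Fast contractile and metabolic lists lay slightly below the controls at 20 to 40 d with few members passing singly, while the list developmental sarcomere lay above. On 4 of the 6 arrays of this window, 20 d replicate 2, both of 30 d and 40 d replicate 1, the manufacturer's Gapdh 3' probe set lay at 0.065 to 0.162 of its 5' probe set, against 0.451 and 0.373 in controls. Developmental sarcomere genes rose in 5 of 14 (6 adjusted over the list alone; adjusted p = 0.0031), and adjusted p = 0.11 with an estimated correlation. The calls of Ankrd1 and Myl6b ended without control replicate 2, and those of Tnni1 and Myh3 without control replicate 1. With single arrays left out, their changes lay at 1.06 to 1.41, 0.844 to 1.406, 1.084 to 1.486 and 0.998 to 1.68 log2. Myh8 changed by 0.13 (SE 0.23), which did not pass. Of 71 oxidative phosphorylation genes 2 fell, Cyc1 and Atp5a1, neither without control replicate 2 (0.23 and 0.192), and none did adjusted over the list alone (adjusted p = 4.3e-07, with a median change of -0.36 log2), and adjusted p = 0.33 with an estimated correlation. No member passed, over all genes or adjusted over the list alone, among 19 glycolysis and glycogen genes (0.00018, median -0.59), 22 fatty acid genes (0.0070, median -0.29) and 25 adult fast contractile genes (0.00079, median -0.54). These had adjusted p = 0.24, 0.41 and 0.28 with an estimated correlation, and 0.146, 0.137 and 0.136 under quantile normalization. Ribosomal protein genes fell in 4 of 32 (4 adjusted over the list alone; 0.00071), with Rps18 at -0.58 (SE 0.14; 0.108 without control replicate 2). That call had adjusted p = 0.10 with an estimated correlation and 0.137 under quantile normalization. Slow contractile genes, with a median change of 0.57, did not differ as a list (0.071), with 1 of 8 higher and 3 adjusted over the list alone, but did under quantile normalization (0.0102), with the mean of a gene's probe sets (0.0248), without control replicate 2 (0.0286) and without the 9 arrays low in the Gapdh 3' probe set (0.0182). Acta1 and Pvalb also stood apart between the 20 d arrays, at 30178 and 978.8 and at 29283 and 866.9.

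**Figure D4:**
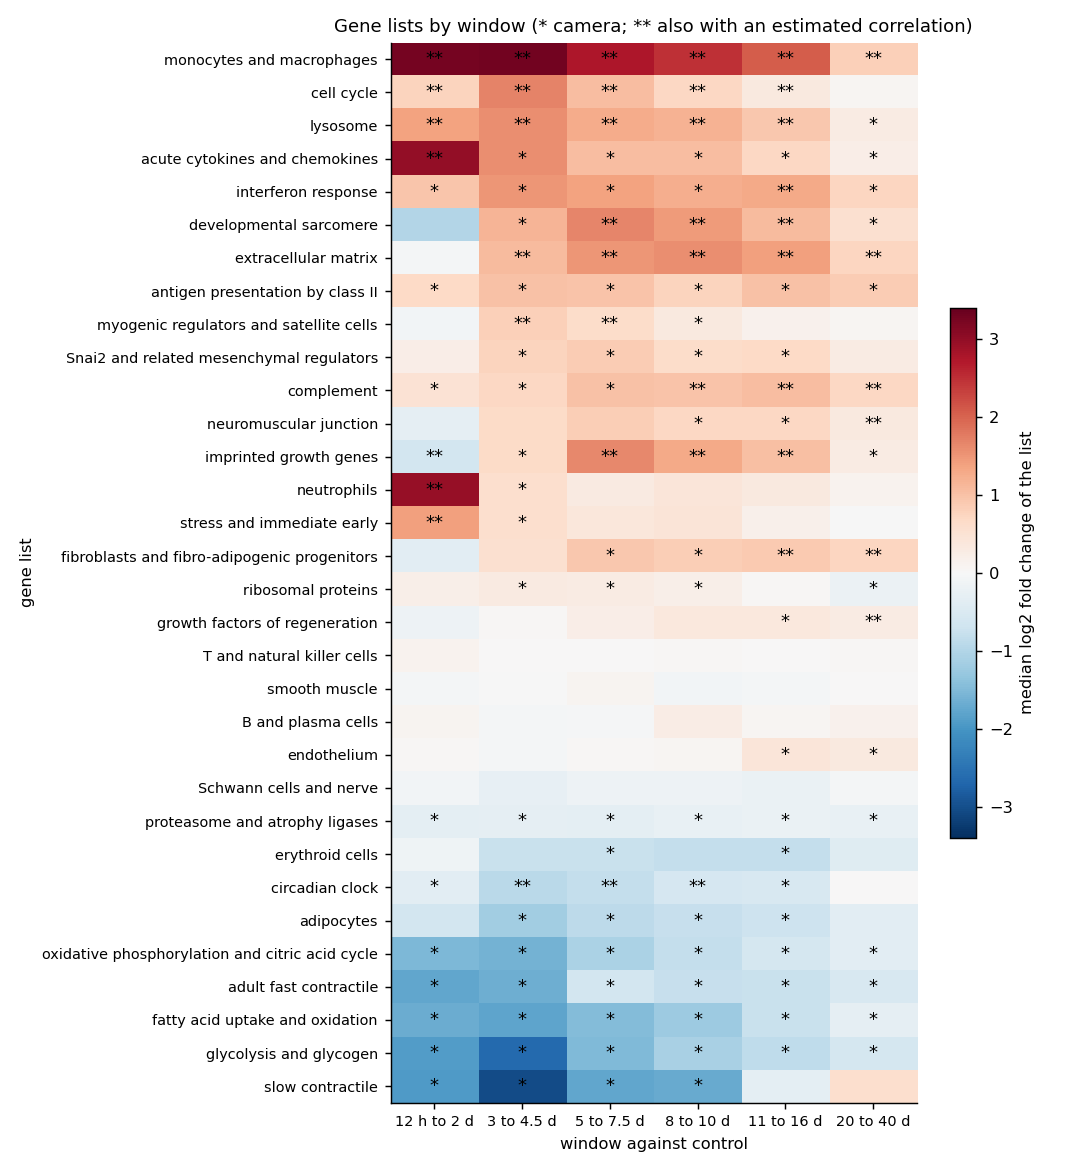
Median log2 change of each of the 32 gene lists (lines of the map) in each of the 6 windows against untreated muscle. A star marks lists called with the preset correlation and a double star those also called with the estimated one, 128 and 44 of 192 squares.

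Neighbouring windows were compared to show when each program turned. From 12 h to 2 d to 3 to 4.5 d, 3305 probe sets changed, 2023 upward (61.2%, but 46.1% under median scaling) and 1282 downward, and 928 with a required change of at least 2-fold. Myh3 rose by 6.22 log2 (SE 0.21), C1qtnf3 by 5.26 (SE 0.18), Myl4 by 5.19 (SE 0.19) and Tnnt2 by 4.62 (SE 0.13). The neutrophil genes S100a8 (-4.48, SE 0.44), S100a9 (-4.57, SE 0.44) and Mmp8, a collagenase (-4.39, SE 0.21), fell. To 5 to 7.5 d, 2537 changed, 1099 upward and 1438 downward (1247 and 1225 under median scaling), and 259 with a required change of at least 2-fold. Cox7a1 (2.28, SE 0.26), Mb (2.06, SE 0.16), Ckmt2 (2.01, SE 0.18) and Myoz1, of the sarcomere (2.13, SE 0.19), rose, while Chil3 (-2.22, SE 0.19), Arg1 (-2.09, SE 0.37) and Gal, a neuropeptide (-1.95, SE 0.09), fell.

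From 5 to 7.5 d to 8 to 10 d there were 293 calls, 123 upward and 170 downward, and 19 with a required change of at least 2-fold. Kcne1l rose by 2.21 log2 (SE 0.20) and the keratin Krt8 by 1.36 (SE 0.20), and Fgfr4 fell (-1.19, SE 0.12). The count was 183 without 8 d replicate 1, 187 without 5 d replicate 2, 87 without the first and last time points of the windows and 178 without the 9 arrays low in the Gapdh 3' probe set. To 11 to 16 d, 783 changed, 380 upward and 403 downward (426 and 390 under quantile normalization), and 41 with a required change of at least 2-fold. Slow fibre genes led the rises, with Myh7 at 2.56 (SE 0.42), Myl3 at 2.38 (SE 0.38), Myl2 at 1.83 (SE 0.35) and Tpm3 at 1.71 (SE 0.20). Adam8 (-1.25, SE 0.16) and Uhrf1, of dividing cells (-1.23, SE 0.17), fell. The count was 181 without 12 h, 4 d, 9 d and 10 d (371 for the pair before), 90 without the first and last time points and 346 without the 9 arrays. To 20 to 40 d, 2342 changed (1332 without the 9 arrays), 982 upward and 1360 downward, and 407 with a required change of at least 2-fold. Inmt (2.54, SE 0.29), Tspan8 (2.27, SE 0.27), Plin4 (1.58, SE 0.21) and Ces1d (1.58, SE 0.22) rose, and Adam8 (-3.20, SE 0.19), Myh3 (-2.56, SE 0.20), C1qtnf3 (-2.46, SE 0.17) and Plagl1 (-2.39, SE 0.17) fell.

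The earlier array asked whether the changes held on another version. There, of 4742 probe sets, 979 changed at 12 h (429 higher, 550 lower), 2049 at 1 d, 2305 at 2 d, 2179 at 4 d and 1261 at 10 d. S100a8 was 5.20 log2 higher at 1 d (SE 0.34, adjusted p = 9.4e-05) and Ccl2 4.56 at 2 d (SE 0.26, adjusted p = 4.4e-05). Myod1 rose by 1.15 (SE 0.28, adjusted p = 0.012) and Myog by 2.66 (SE 0.18, adjusted p = 4.6e-05) at 4 d, and Myf6 fell (-2.14). At 10 d Mmp12 rose by 2.63 (SE 0.18), Postn by 4.44 (SE 0.39) and Myog by 1.51 (SE 0.18). Snai2 rose at 10 d (0.97, SE 0.23, adjusted p = 0.017), while its change at 4 d, 0.35 (SE 0.23), did not pass (adjusted p = 0.254). Of 309 results of named genes measured on both versions, 80 calls of the later version did not pass on the earlier and 1 more, Chrna1 at 12 h to 2 d, also changed sign there. The 80 included Lipa and Il7r at 12 h to 2 d, Prc1 and Peg3 at 3 to 4.5 d, and Ryr1 and Chrng at 8 to 10 d. On the earlier version, 3 to 4.5 d was represented by 4 d alone and 8 to 10 d by 10 d alone. Each of these times had 2 arrays there, and the floor was higher than on the later version. For these windows, a call that did not pass is therefore not a failed repeat of the same comparison.

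At 12 h the higher share on the earlier array was 43.8%, but 54.3% under median scaling. The 12 h count was 2115 without 12 h replicate 1, 533 without control replicate 2 and 598 without control replicate 1. The 1 d count was 1357 without control replicate 2 and 1358 without 1 d replicate 1, and the 4 d count 1438 without 4 d replicate 2. The 10 d count was 558 without 10 d replicate 2, 682 without 10 d replicate 1 and 689 without control replicate 2. With a required change of at least 2-fold the counts were 492, 1286, 1425, 1322 and 633, in order of time.

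Across the 4742 probe sets, log2 changes on both versions had Pearson r = 0.805 at 12 h, 0.834 at 1 d, 0.835 at 2 d, 0.818 at 4 d and 0.760 at 10 d, with Spearman rho = 0.785, 0.840, 0.848, 0.826 and 0.767. These are correlations across genes, and genes are not independent replicates. The control codes are the same on both versions, so noise shared through the controls was simulated. It gave r = 0.426 and a covariance of 0.0389, against observed covariances of 0.757, 1.382, 1.5426, 1.3355 and 0.601. The 12 h samples share codes as well, which the simulation did not cover, so the agreement at 12 h has no matching value without change. Set against the 30 and 40 d arrays in place of the later version's controls, r was 0.794, 0.803, 0.785 and 0.683 at 1, 2, 4 and 10 d. The sign was the same on both versions for 76.0%, 80.7%, 81.4%, 79.1% and 73.0% of the 4742 probe sets, in order of time, against 67.0% simulated from the shared controls alone. The simulation applied no floor. In the data, a change of exactly 0 at the floor on 1 version alone counted as a different sign, so the 67.0% is not a matched value. Of the probe sets picked for a change of at least 2-fold on both versions, for which nothing was simulated, 594 of 594, 1117 of 1118, 1202 of 1203, 1114 of 1118 and 568 of 568 had the same sign.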

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

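The tests of the 4 d arrays and of the bright probe sets, the comparison of 4 d with its neighbours, and the genes named as examples of opposite changes were chosen only after the results were seen.

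Probe sets called in opposite directions in neighbouring windows, with a difference that passed too, stood out. Between 12 h to 2 d and 3 to 4.5 d there were 70, 59 of them lower and then higher. They were picked by these calls, which makes a test of the difference on them nearly certain to pass, so its p-values are not given. Myl4, the embryonic light chain, went from -1.38 to 3.82 log2 against untreated muscle, Cdkn1c from -2.13 to 2.38 and Cdh15, the cadherin of satellite cells, from -1.30 to 1.54. Myh3 went from -1.24 to 4.98. For Myh3 at 12 h to 2 d the adjusted p ranged from 0.000487 to 0.456 over the alternatives, and with the doubled floor, which gave the latter, the early fall did not pass. The other 11 were higher and then lower, such as Cebpb, a transcription factor of inflammation (1.62, then -1.15), and Hbegf, a growth factor (0.78, then -0.75). Between 3 to 4.5 d and 5 to 7.5 d there were 4, with Itm2a lower and then higher (-0.57, then 0.93) and the chemokine Cxcl14 higher and then lower (0.73, then -0.69). No explanation was tested for these.

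The arrays of 12 h stood apart in lymphocyte genes. On replicate 2 the 16 genes of the list B and plasma cells lay 1.807 log2 above replicate 1 on average, 11 of them over 2-fold, with Cd79a at 3359 against 361.7, Cd79b at 2334 against 187.8 and the abundant antibody chain Ighm at 8114 against 2247 (3334 in untreated muscle). A shift of the whole array was argued against, since the difference lay at percentile 100 of matched random lists, of which the highest was 1.061. On the earlier version, the arrays with the same codes differed by 1.023 log2 in the same direction over the 4 genes of the list that were tested and above the floor at 12 h. With 2 more genes above the floor there but below the filter, Cd79a and Blk, the mean was 1.11, and over all 14 genes, with those at the floor counted as 0, it was 0.476. By the genes above the floor, a candidate explanation is lymphoid tissue, such as a node, in that RNA. More B cells within that muscle stay open as well and were not tested.

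The 4 d arrays differed from 3.5 and 4.5 d at 813 probe sets, more than any other time set against its neighbours. A processing batch shared with 10 d is a candidate explanation. Across these probe sets the deviation of 10 d from 9.5 and 11 d correlated with that of 4 d at Pearson r = 0.643, with the same sign for 77.2%, and genes are not independent replicates. Among the arrays set against 10 d, 9.5 d replicate 2 and 11 d replicate 1 were low in the Gapdh 3' probe set. At 10 d itself 51 probe sets differed from 9.5 and 11 d. The difference of the controls from 30 and 40 d correlated with the deviation of 4 d at 0.329. A batch that also holds the controls, which every window uses, was not excluded. An earlier stage of repair or a larger injury in the 4 d muscles cannot be told apart from a batch. The correlation with the difference of 3 d from 5 d was 0.377, between the limits set for and against. Both 4 d arrays were also low in the manufacturer's b-actin 3' probe set, at 0.045 and 0.018 of its 5' probe set against 0.969 and 0.989 at 3.5 d and 0.594 and 0.851 at 4.5 d, a sign that 10 d did not share (0.702 and 0.765). A fault shared with other such arrays cannot be told apart either, since the deviation of 4 d correlated at -0.233 with 5 d replicate 1 minus 2 and at 0.333 with 12 h replicate 2 minus 1. The labels give no batch and no hour of collection. For the clock genes among these probe sets, a different hour from 3.5 and 4.5 d cannot be told apart from the other causes.

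Some bright probe sets were low on some arrays. At an intensity over 8000, 17 probe sets differed more than 8-fold between the arrays of a time in 24 cases, which lay in 8 pairs of arrays, Acta1 in 5 of them. On 8 arrays, 12 h replicate 2, 5 d replicate 1 and both of 1, 2 and 4 d, the manufacturer's b-actin 3' probe set lay at 0.018 to 0.233 of its 5' probe set, against 0.571 to 1.377 elsewhere. On 9 others, 9.5 d replicate 2, 11 d replicate 1, 12 d replicate 2, 14 d replicate 2, 16 d replicate 1, 20 d replicate 2, both of 30 d and 40 d replicate 1, the Gapdh 3' probe set lay at 0.044 to 0.162 of its 5' probe set, against 0.314 to 0.970 elsewhere. In 15 of the 24 cases the lower value lay on one of these 9 arrays, and in 6 on one of the 8. Both arrays of 1 and 2 d are among the 8, so a case at these times counted whichever array was lower. The 6 therefore cannot show a link with the b-actin 3' probe set.

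Less of the 3' end in the whole RNA was argued against by the 3'/5' ratios of other control genes, at least 0.589 for Gapdh on the 8 arrays and at least 0.902 for b-actin, transferrin receptor and pyruvate carboxylase on the 9. Degraded RNA, which raises these ratios, was argued against by at most 0.970 for Gapdh on the 8 and at most 1.377 for b-actin on the 9. Transferrin receptor and pyruvate carboxylase had medians of 3.298 and 2.333 on the 8, against 3.530 and 1.921 on the arrays without a low b-actin 3' probe set, though transferrin receptor reached 12.42 on 1 d replicate 2 and pyruvate carboxylase 3.897 on 1 d replicate 1. On the 9 their medians were 3.922 and 2.071, against 3.369 and 1.919 on the arrays without a low Gapdh 3' probe set. The 2 control arrays, which every window uses, stood at 4.415 and 4.038 for pyruvate carboxylase and at 0.451 and 0.373 for Gapdh. Whether their RNA differed in quality was not tested. A ceiling of the signal was argued against for b-actin alone, since 3 of the 8 arrays had a highest value under the median of the other arrays. For Gapdh and for the 24 cases it cannot be told apart from other causes. On 7 of the 9 arrays the highest value lay under the median of the other arrays, as on 5 of the 6 arrays with Acta1 under 3500 it lay under that of the median array, and in 17 of 24 cases the lower value lay on the array with the lower ceiling, against 12 by chance, though cases from the same 8 pairs are not independent. No biological explanation was tested.

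Other splits of the same time points into windows of the same sizes were counted for each neighbouring pair. All 35 and 56 were run for the first and last pair, and for the others 100 were run, the real one and others drawn at random, out of 210, 462 and 126. From 12 h to 2 d to 3 to 4.5 d, 1 of 35 splits, the real one, gave as many as 3305 calls (highest other 3018). From there to 5 to 7.5 d 1 of 100, again the real one, gave 2537 (highest other 2294). From 5 to 7.5 d to 8 to 10 d, 2 of 100 gave as many as 293 (highest other 322). To 11 to 16 d 2 of 100 gave as many as 783 (highest other 869). From 11 to 16 d to 20 to 40 d, 3 of 56 gave as many as 2342. The highest was 2660, for 11, 12 and 13 d against the rest, so chance is not excluded for that count. Because the times are ordered, a steady drift would favour a split of early from late times wherever its edge lies. These shares therefore cannot show that a change falls at the window edges used, and they do not exclude chance for any pair.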

How the results depend on the processing

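The windows without 12 h, 4 d, 9 d or 10 d, 4 d and 10 d alone, and the fits without bright probe sets, without the 8 arrays low in the b-actin 3' probe set or without the 9 low in the Gapdh 3' probe set were chosen only after the results were seen, and the other alternatives were planned. No list that was called changed direction under any alternative run for it. Of the calls of named genes, 3 changed sign without passing the other way, Txk at 5 to 7.5 d and 8 to 10 d without control replicate 1 (0.155 and 0.096, from -0.762 and -0.821) and Chrna1 at 12 h to 2 d on the earlier array (0.038, from -1.329). Quantile normalization, median scaling, other floors, a variance trend, and 30 and 40 d in place of the controls kept each count of changed probe sets within 1.5 times. The balance of direction was less stable. Median scaling turned a majority of higher probe sets into one of lower at 3 to 4.5, 5 to 7.5, 8 to 10 and 11 to 16 d (46.2%, 46.3%, 47.4% and 48.7% higher) and between the first pair of windows (46.1%), and turned the balance the other way for the next pair (50.4%) and at 12 h, 2 d and 4 d on the earlier array (54.3%, 52.9% and 52.8%). Quantile normalization turned it at 3 to 4.5, 5 to 7.5 and 8 to 10 d (48.5%, 47.6% and 48.3%), from 8 to 10 d to 11 to 16 d (52.2%) and at 4 d on the earlier array (50.1%). On the earlier array the halved floor turned it at 12 h, 2 d and 4 d (51.5%, 50.4% and 52.1%) and the doubled floor at 10 d (45.3%). Beyond these, the halved floor, no filter, the variance trend, windows without their first and last time points and the window without 12 h turned 1 balance each, and a required change of at least 2-fold 5 of 16. A required change of at least 2-fold, which removes smaller changes by construction, left 2525, 2920, 2248, 1833, 1266 and 361 in the 6 windows in order, 928, 259, 19, 41 and 407 between neighbouring windows, and 492, 1286, 1425, 1322 and 633 on the earlier array. Without the filter on dim probe sets the earlier array gave 524 at 12 h and 751 at 10 d. Windows without their first and last time points, which hold fewer arrays, gave 87 (5 to 7.5 d to 8 to 10 d) and 90 (8 to 10 d to 11 to 16 d). The latter was 181 without 12 h, 4 d, 9 d and 10 d. Without the time points whose codes share a number, 11 to 16 d was left with 16 d alone and gave 807. With each array left out in turn, a lone array being assumed to vary like the other groups, the counts ranged from 2443 to 3675 at 8 to 10 d, 1659 to 2945 at 11 to 16 d, 417 to 884 at 20 to 40 d, 183 to 422 from 5 to 7.5 d to 8 to 10 d, and on the earlier array 533 to 2115 at 12 h, 1357 to 1929 at 1 d, 1438 to 1697 at 4 d and 558 to 849 at 10 d. Without the 9 arrays low in the Gapdh 3' probe set the counts were 476 at 20 to 40 d, and 178, 346 and 1332 between the last 4 windows in order. Beyond the smaller numbers of arrays and the larger minimum change, the cause was not tested.

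With the number and letters in the sample codes as a replicate block, the counts were 4377, 4851, 4167, 3661, 2930 and 812 in the 6 windows and 5769 over the time course. In the 18 groups whose codes differ in number, deviations between arrays numbered alike had a median r of 0.003 over 153 pairs of groups. The numbers thus showed no effect shared across times. This cannot show whether the 2 arrays of a group came from 1 mouse. In the other 9 groups the codes share a number and differ in the letters LL and RL. Of 192 list results, quantile normalization ended 10 and gained 5, the doubled floor ended 3 and gained 1, the mean of a gene's probe sets ended 4 and gained 1, and leaving out control replicate 1 or 2 ended 5 and 5 and gained 2 and 5. Of the 96 from 8 d on, leaving out the 9 arrays ended 5 and gained 2. Of 776 results of named genes, 22 did not pass under quantile normalization, and of 754 calls 171 ended without at least 1 of the control arrays, and the peak time of 12 of 32 lists was kept with each array left out. Signal near the floor limits folds, which are lower bounds for genes at the floor in both controls.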

Other observations

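The comparisons of single time points with their neighbours, and the genes and lists named from them, were chosen only after the results were seen.

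Inflammatory genes stood out on the 2 arrays of 9 d. Against 8.5 and 9.5 d, 293 probe sets differed at 9 d, 180 higher and 113 lower. Il1b, interleukin 1 beta, stood at 6627 against 69.4 at the neighbouring times, where 2 of 4 arrays lay at the floor (log2 difference at least 6.30, SE 0.65, adjusted p = 2.1e-07), S100a8 at 9489 against 143.3 (5.58, SE 0.70), Saa3, an acute phase protein, at 12720 against 266.6 (5.54, SE 0.92) and Arg1 at 3859 against 131.4 (4.86, SE 0.69). Of 34 acute cytokines and chemokines 15 were higher (camera adjusted p = 6.9e-24, and 0.0018 with an estimated correlation), and of 22 neutrophil genes 7 were (1.7e-12, and 0.017 with an estimated correlation). Stress genes such as Bcl3 (3.86, SE 0.49) and Nfkbia (2.06, SE 0.22) were higher in 7 and lower in 1 of 47 (0.00041), and adjusted p = 0.18 with an estimated correlation. Col1a1, a collagen, was higher (1.18, SE 0.30), while the receptor Fgfr4 (-1.21, SE 0.24) and Myod1 (-0.65, SE 0.18) were lower. Both 9 d arrays showed this rise, with scores of 2.38 and 1.51 for the list neutrophils. The same list scored 0.56 and 0.41 at 8.5 d, 0.52 and 0.45 at 9.5 d, and 1.74 and 1.53 at 13 d. Whether the rise belongs to repair or to the muscles or arrays of 9 d was not tested.

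At 4 d, fibre genes lay below their levels at the neighbouring times. Slow contractile genes were lower in 5 of 8 (camera adjusted p = 4.7e-06, and adjusted p = 0.14 with an estimated correlation), with Myl2 at the floor on both arrays against 1645 at 3.5 and 4.5 d (-4.58, SE 0.69, a bound set by the floor) and Mb at 812 against 4396 (-2.42, SE 0.31). Imprinted growth genes were lower in 4 of 18 (0.014, and adjusted p = 0.13 with an estimated correlation), with Grb10 at -2.68 (SE 0.40). Circadian clock genes were lower in 3 and higher in 1 of 13 (0.028, and adjusted p = 0.14 with an estimated correlation). Among them Cry1 stood at -1.03 (SE 0.13), against Dbp at 1.63 (SE 0.48). For these genes a different hour of collection was not tested. Ribosomal protein genes were higher in 8 and lower in 1 of 32 (2.8e-05, and adjusted p = 0.099 with an estimated correlation), and acute cytokines and chemokines, such as Ccl2 (1.48, SE 0.29) and Ccl4 (2.07, SE 0.56), in 4 of 34 (0.0011, and adjusted p = 0.28 with an estimated correlation). The count of the window from 3 to 4.5 d was 4183 with 4 d alone.

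List scores peaked in sequence. The stress list was highest at 12 h, the neutrophil list at 1 d, the macrophage list at 2 d, the cell cycle and lysosome lists at 3 d, the myogenic list at 3.5 d, the neuromuscular junction list at 4.5 d, the developmental sarcomere and imprinted lists at 5.5 d, the matrix list at 7 d and the fibroblast list at 10 d. With each array left out in turn the neutrophil peak moved between 12 h and 1 d, the myogenic one between 3.5 and 4.5 d, the matrix one between 5.5 and 7 d and the fibroblast one between 10 and 14 d. The oxidative phosphorylation list was lowest at 2 d and the glycolysis and fast contractile lists at 3 d, which moved between 1 and 2 d, 3 and 4 d, and 2 and 4 d with each array left out in turn.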
